A study of Homo sapiens with 18 samples.

How the data were processed

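The data were gene-level read counts from 18 bulk RNA-seq libraries of LX-2, an established human hepatic stellate cell line. Stellate cells are the liver cells that deposit matrix in fibrosis. Per the labels' protocols, subcultures were kept in serum-free medium for 1 h and then given thrombin, the clotting protease, at 1 U/mL or serum-free medium alone for 4, 24 or 48 h, and total RNA was enriched for poly(A) transcripts before library construction. The treatment and the time made 6 groups of 3 libraries, taken from the labels alone.

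The deposited table held raw counts per gene symbol, with no normalization by the authors visible in the values, which were whole numbers with a different total in each column. Per the submitters' processing notes, cutadapt 4.9, Bowtie2 2.5.4, SAMtools 1.21 and DESeq2 were used and GRCh38 (hg38) was listed as the build; the role of each tool, the counter, the gene annotation and the strand setting were not given in the sources used here. Bowtie2 does not split reads across introns, so if it aligned reads to a genome, reads over splice junctions would be lost in every library alike, and if it aligned to transcripts, reads shared by related transcripts would be divided by a rule not given. Genes with near-identical copies or pseudogenes (KRTAP2-3, ANXA2, ACTB, KRT8, KRT18, the histones and the ribosomal proteins) and genes that overlap another gene are therefore uncertain in level. Whether reads of a gene and of its antisense partner were told apart is not known, since the strand setting was not given. All 18 columns were matched to a library by name, and 0 columns were left over. The table had 28278 symbols and 0 entries without a gene name; 4439 symbols had no count in any library. Of the symbols, 26998 (95.5%) were found in the RefSeq gene table of GRCh38.p14, which gave the coordinates.

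Counts were analysed with edgeR 4.0.16 in R 4.3.3. Genes were kept by filterByExpr over the 6 groups (minimum count 10, minimum total 15), which left 15353 genes holding at least 99.9% of each library's counts. Libraries were scaled by TMM, with factors from 0.945 to 1.031. A quasi-likelihood model with a mean per group was fitted to all 18 libraries with robust dispersion (12 residual degrees of freedom, biological coefficient of variation 9.07%), and each contrast was tested two-sided with Benjamini-Hochberg adjustment over the 15353 genes; "called", "rose" and "fell" mean an adjusted p under 0.05. Standard errors of log2 fold changes were taken from the fold change and its F statistic. Levels are TMM-scaled CPM, given as mean ± SD over the 3 libraries of a group. The contrasts were thrombin against control at each time, the difference of that effect between each pair of times, and control against control between successive times. The titles number the libraries of each group 12, 13 and 14 after a letter p whose meaning is not stated, so whether they came from separate cultures is not given in the sources used here, and p-values measured the spread between these libraries, which may be technical.

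Before the data were examined, 41 gene lists (980 entries, 965 in the table) were fixed, among them markers of hepatocytes, endothelial cells, macrophages and cholangiocytes as other cell types, and replication-dependent histones as a sign of RNA quality. Lists with at least 3 tested genes (40; the list of genes encoded by the mitochondrial genome had no member in the table and was not analysed here) were tested with limma 3.58.1 camera on log2 CPM (prior count 2) with a preset correlation of 0.01, adjusted over the 40 lists. Camera with an estimated correlation and fry were the alternatives. List tests on the differences between times and on the control comparisons were added after the data were seen. Correlations of fold changes were taken across genes, which are not independent replicates.

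The genes named were chosen by a rule written before the data were examined. For each thrombin comparison these were the 8 largest called increases and decreases whose 3 libraries lay wholly above or below the other 3, with a mean raw count of at least 50 in the higher group and leaving out unnamed loci, antisense genes, pseudogenes, XIST and genes of chromosome Y. They also included up to 4 members with the smallest adjusted p of each list called or with at least 25% of its tested members called, and 18 anchor genes of thrombin signalling and stellate cell biology. For the other comparisons the 5 largest changes in each direction were taken. Any gene outside the rule is said to be so where it is named. Values of some of these genes and lists are not reported here.

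The procedure was tested on simulated data made from the real genes' means, dispersions and library sizes, with 200 of 15353 genes changed. At 4 h, 74.6%, 88.1% and 93.9% of the genes changed 1.5-, 2- and 4-fold were called, and 4.47% of calls were false. At 24 h the shares were 79.1%, 82.1% and 95.5%, with 7.57% false. At 48 h they were 79.1%, 86.6% and 95.5%, with 6.95% false. These rates are for edgeR, from a single simulated set per time. In the real data 11.8% of genes were called at 4 h and 17.6% at 24 h, so the rates need not hold there. None of 40 unchanged random lists was called by camera in the simulated comparison at 4, 24 or 48 h (0 of 40 each); the genes were simulated independently, so this did not test the effect of correlated genes. Alternatives were the DESeq2 1.42.0 Wald test, DESeq2 size factors in edgeR, no low-count filter, the replicate number as a block, a fit of the 6 libraries of one time, and each library left out in turn. A fit without the 4 h libraries and one without the libraries numbered 12 were added after the data were seen. Library totals ranged from 14431044 to 23270601 counts.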

Results

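RNA-seq counts were obtained from LX-2 hepatic stellate cells given thrombin or serum-free medium, with 3 libraries in each of 6 groups. Library totals ranged from 14431044 to 23270601 counts, and the 10 most abundant genes took between 4.00% and 5.51% of each library. The design addresses how thrombin changes the transcripts of stellate cells at 4, 24 and 48 h. The thrombin effect at 4 h and 24 h had opposite signs for 948 of the 961 genes called at both times, and the libraries labelled thrombin 4 h and control 24 h differed in 11 of 15353 genes. Groups are therefore named as labelled throughout. Every direction, and every count of genes whose effect differs between times, rests on those labels. Replicates are named by the numbers in the labels (12, 13 and 14).

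**Figure D1:**
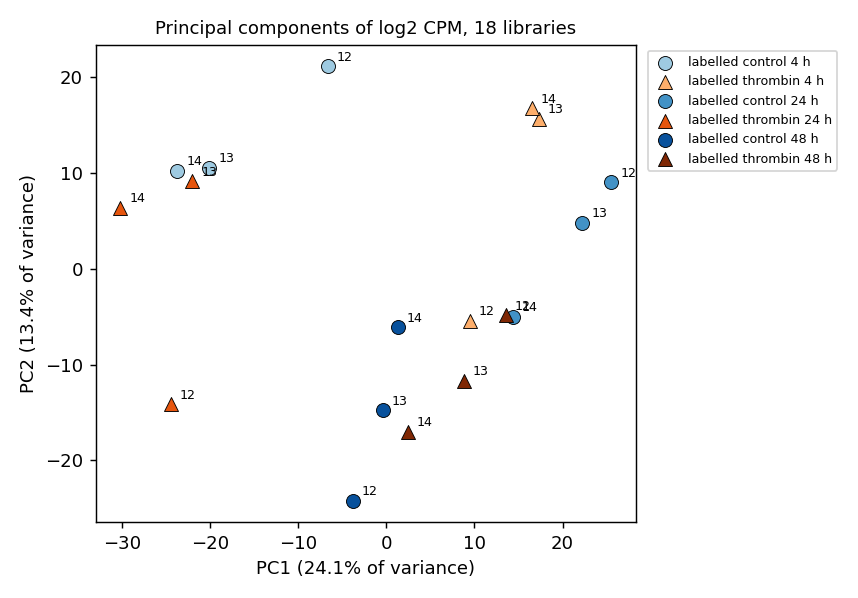
Principal components of log2 CPM for the 18 libraries, coloured by labelled group, with replicate numbers; circles are control and triangles thrombin. PC1 (24.1% of variance) places the libraries labelled control 4 h and thrombin 24 h on one side and those labelled thrombin 4 h and control 24 h on the other. On PC2 (13.4% of variance) the libraries numbered 12 lie apart from the others of their group in thrombin 24 h (-14.12 against 6.334 and 9.066), thrombin 4 h (-5.454 against 15.62 and 16.72) and control 4 h (21.06 against 10.17 and 10.49). The remaining groups spread along PC2 from -5.002 to 8.981 (control 24 h), -24.17 to -6.095 (control 48 h) and -17.01 to -4.888 (thrombin 48 h).

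At 4 h, 11 of 24 SRF and MRTF targets of the actin cytoskeleton, 8 of 15 coagulation genes and 5 of 12 chemokines fell in the libraries labelled thrombin relative to those labelled control. These 3 lists were called lower by camera with the preset correlation, and had adjusted p = 0.121, 0.178 and 0.178 with an estimated correlation. TAGLN, which encodes the actin-binding protein transgelin, measured 72.8 ± 5.77 CPM (SD, n = 3) in control and 36.2 ± 0.951 CPM in thrombin, a log2 fold change of -1.01 ± 0.12 (SE, edgeR adjusted p = 6.59e-06). PLAT, which encodes tissue plasminogen activator, changed by -1.36 ± 0.14 (edgeR adjusted p = 2.68e-06), and LOXL2, a collagen-crosslinking enzyme, by -0.93 ± 0.09 (edgeR adjusted p = 8.82e-07). In all, 965 genes rose and 848 fell of 15353 tested, and 138 of these changed at least 2-fold, 26 upwards and 112 downwards.

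By the naming rule, the largest called decreases at 4 h were in the hair keratin-associated gene KRTAP2-3 (-3.40 ± 0.41, level uncertain because of a near-identical copy), the neutrophil chemokine gene CXCL8 (-2.45 ± 0.45), the keratin gene KRT34 (-2.29 ± 0.26), the hyaluronan synthase gene HAS2 (-2.25 ± 0.52), SERPINB2 (-2.10 ± 0.50), which encodes an inhibitor of plasminogen activators, the reelin gene RELN (-1.99 ± 0.35), FOLR3 (-1.94 ± 0.32) and the endocan gene ESM1 (-1.93 ± 0.47). The largest called increases by that rule were in PPL (1.40 ± 0.25), which encodes the cytolinker periplakin, METTL7A (1.28 ± 0.22), LRRC4B (1.27 ± 0.27), the complement gene C3 (1.15 ± 0.190 to 2.70 ± 1.58 CPM), NXPH3 (1.16 ± 0.23), the Hedgehog transcription factor gene GLI1 (1.08 ± 0.15), the cyclin-dependent kinase gene CDK18 (1.08 ± 0.16) and ANKRD34A (1.08 ± 0.15). GLI1 measured 8.96 ± 1.31 CPM in control and 19.1 ± 1.28 CPM in thrombin (edgeR adjusted p = 2.76e-05).

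Of the 24 SRF and MRTF target genes of the actin cytoskeleton, 1 rose, 11 fell and 12 were not called (adjusted over the list alone, 1 rose and 14 fell); TPM1, a tropomyosin gene, changed by -0.66 ± 0.08, CALD1, which encodes caldesmon, by -0.81 ± 0.11 and ACTB by -0.44 ± 0.07. The list was called lower by limma camera (adjusted p = 2.65e-07), with adjusted p = 0.121 with an estimated correlation. Of 15 coagulation and fibrinolysis genes, 0 rose and 8 fell (adjusted over the list alone, 1 rose and 9 fell). For coagulation genes camera gave adjusted p = 0.000166, and adjusted p = 0.178 with an estimated correlation. The tissue factor gene F3 changed by -0.66 ± 0.14 (edgeR adjusted p = 0.00281). Of 12 chemokine genes 0 rose and 5 fell (adjusted over the list alone, 0 and 6), among them CCL26 (-1.91 ± 0.31) and CXCL6 (-0.96 ± 0.17). Chemokines had a camera adjusted p = 0.00293, and adjusted p = 0.178 with an estimated correlation. Of 20 TGF-beta and SMAD response genes 0 rose and 5 fell (adjusted over the list alone, 0 and 6). For TGF-beta and SMAD genes camera gave adjusted p = 0.00303, and adjusted p = 0.197 with an estimated correlation. YAP and TAZ targets had 1 higher and 7 lower of 21 (adjusted over the list alone, 2 and 10), with the insulin-like growth factor carrier gene IGFBP3 at -1.54 ± 0.17. YAP and TAZ targets had a camera adjusted p = 0.00818, and adjusted p = 0.448 with an estimated correlation. Ribosome biogenesis genes had 0 higher and 6 lower of 29 (adjusted over the list alone, 0 and 7), among them NCL (-0.34 ± 0.07) and NOP56 (-0.30 ± 0.07). For ribosome biogenesis genes camera gave adjusted p = 3.03e-05, and adjusted p = 0.178 with an estimated correlation. Interferon-stimulated genes were the only list of the 40 called higher at 4 h, with 5 rising and 1 falling of 30 (adjusted over the list alone, 6 and 1). Interferon-stimulated genes had a camera adjusted p = 0.0197, and adjusted p = 0.328 with an estimated correlation. TAP1, an antigen-peptide transporter gene, rose by 0.63 ± 0.09 and SAMD9 fell by 0.91 ± 0.15.

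Among the protease-activated receptor (PAR) genes at 4 h, F2R, which encodes the main thrombin receptor PAR1, rose by 0.41 ± 0.08 (edgeR adjusted p = 0.00105). Its level went from 174.7 ± 15.6 to 232.2 ± 9.27 CPM. F2RL1, which encodes PAR2, had a log2 fold change of 0.43 ± 0.21 that was not called (edgeR adjusted p = 0.184), and F2RL3 had at most 2 raw counts in any library and was not tested. THBD, which encodes thrombomodulin, fell by 1.28 ± 0.38 (edgeR adjusted p = 0.0289), and CCL2, HBEGF and COL1A1 fell by 0.78 ± 0.23, 0.54 ± 0.13 and 0.33 ± 0.10. The immediate early gene EGR1 measured 37.7 ± 28.4 CPM in control and 53.4 ± 17.8 CPM in thrombin and was not called (edgeR adjusted p = 0.517), and CCN1, CCN2, ACTA2, COL1A2, TIMP1, IL6 and F2RL2 were not called either. The replication-dependent histones, whose transcripts mostly lack poly(A), moved with these groups, with 0 rising and 1 falling of 19 (adjusted over the list alone, 0 and 1). For histones camera gave adjusted p = 0.00353, and adjusted p = 0.197 with an estimated correlation. The mitosis and G2/M list was also called lower at 4 h, so RNA quality and the cell cycle cannot be told apart for the histones. Epithelial markers were also lower, with 0 rising and 2 falling of 6 (adjusted over the list alone, 0 and 5), KRT8 by -0.46 ± 0.13 and KRT18 by -0.36 ± 0.11. Epithelial markers had a camera adjusted p = 0.0156, and adjusted p = 0.197 with an estimated correlation.

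Of 40 lists, 17 were called at 4 h, 1 higher and 16 lower, and 0 of them with an estimated correlation. A split of the same libraries that mixed the labels also called 17. The count of genes that rose at 4 h was 560 without control replicate 13, 509 without control replicate 14, 525 without thrombin replicate 13, 425 without thrombin replicate 14 and 570 in a fit of the 6 libraries of 4 h, and the counts that fell without those 4 libraries in turn were 459, 499, 463 and 415. Without all libraries numbered 12, an alternative added after the data were seen, 1772 genes rose and 1788 fell.

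At 24 h, 22 of 24 SRF and MRTF targets, 14 of 20 TGF-beta and SMAD response genes and 6 of 12 chemokines rose in the libraries labelled thrombin, with adjusted p = 0.00238, 0.0447 and 0.0408 with an estimated correlation. Of 25 cholesterol synthesis and uptake genes 20 fell, with adjusted p = 0.0514 with an estimated correlation. TAGLN measured 25.1 ± 1.92 CPM in control and 144.2 ± 5.09 CPM in thrombin (SD, n = 3), a log2 fold change of 2.52 ± 0.13 (edgeR adjusted p = 8.21e-13, the smallest of all genes). The matricellular gene THBS1 rose by 1.40 ± 0.12. F2R fell from 273.9 ± 8.72 to 153.2 ± 11.5 CPM (-0.84 ± 0.08, edgeR adjusted p = 2.14e-08). In all, 1389 genes rose and 1311 fell, and 384 changed at least 2-fold, 231 upwards and 153 downwards.

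By the naming rule, the largest called increases at 24 h were in KRTAP2-3 (4.48 ± 0.49, with the same uncertainty), the natriuretic peptide gene NPPB (4.17 ± 0.35), the calcium-regulated transcription factor gene NFATC2 (3.66 ± 0.25), RELN (3.38 ± 0.36), CXCL8 (3.33 ± 0.49), the monocyte chemokine gene CCL7 (2.74 ± 0.36), SERPINB2 (2.70 ± 0.55) and the cation channel gene TRPC4 (2.67 ± 0.28). NPPB was low, at 0.320 ± 0.237 CPM in control and 5.88 ± 0.579 CPM in thrombin, while CXCL8 went from 4.58 ± 2.14 to 46.5 ± 17.8 CPM. The largest called decreases by that rule were in PPL (-2.55 ± 0.26), GASK1B (-1.96 ± 0.42), METTL7A (-1.81 ± 0.25), CDK18 (-1.70 ± 0.17), SLC35F4 (-1.55 ± 0.30), F2RL1 (-1.52 ± 0.23), SLITRK4 (-1.48 ± 0.20) and the myosin gene MYO7A (-1.47 ± 0.24). In GRCh38.p14, TAGLN lies on chromosome 11 from 117199294 to 117207465, CXCL8 on chromosome 4 from 73740569 to 73743716 and F2R on chromosome 5 from 76716126 to 76735770, all protein-coding genes.

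Of the 24 SRF and MRTF targets, 22 rose, 1 fell and 1 was not called at 24 h (adjusted over the list alone, 22 rose and 1 fell), with CALD1 at 1.54 ± 0.12, FHL2 at 0.94 ± 0.07 and TPM1 at 0.85 ± 0.08. For SRF and MRTF targets camera gave adjusted p = 1.53e-19, and adjusted p = 0.00238 with an estimated correlation. TGF-beta and SMAD response genes had 14 higher and 0 lower of 20 (adjusted over the list alone, 14 and 1), among them TGFBI (1.32 ± 0.11) and the inhibitory SMAD gene SMAD7 (0.90 ± 0.11). TGF-beta and SMAD genes had a camera adjusted p = 1.01e-06, and adjusted p = 0.0447 with an estimated correlation. Chemokines had 6 higher and 0 lower of 12 (adjusted over the list alone, 7 and 0), with the monocyte chemokine gene CCL2 at 2.20 ± 0.23 and CXCL6 at 1.94 ± 0.19. For chemokines camera gave adjusted p = 3.06e-05, and adjusted p = 0.0408 with an estimated correlation. Matrix proteases and inhibitors had 9 higher and 0 lower of 25 (adjusted over the list alone, 10 and 0), with ADAM19 at 1.63 ± 0.14, the metalloproteinase inhibitor gene TIMP3 at 1.20 ± 0.08 and the gelatinase gene MMP9 at 1.30 ± 0.20. Matrix proteases had a camera adjusted p = 0.000317, and adjusted p = 0.0447 with an estimated correlation. These 4 lists were the ones called with an estimated correlation at 24 h.

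YAP and TAZ targets had 15 higher and 0 lower of 21 at 24 h (adjusted over the list alone, 17 and 0), with CCN1, which encodes a matricellular protein, at 0.96 ± 0.09 and CRIM1 rising from 286.2 ± 17.3 to 615.7 ± 20.1 CPM. For YAP and TAZ targets camera gave adjusted p = 1.79e-12, and adjusted p = 0.0514 with an estimated correlation. Growth factor genes had 13 higher and 4 lower of 26 (adjusted over the list alone, 13 and 4), including FGF2 (1.33 ± 0.10), FGF1 (1.52 ± 0.13) and PDGFA (0.92 ± 0.10). Growth factors had a camera adjusted p = 7.39e-05, and adjusted p = 0.054 with an estimated correlation. NF-kappa-B targets had 12 higher and 0 lower of 22 (adjusted over the list alone, 13 and 0), among them TNFAIP3 (1.13 ± 0.17), which encodes a feedback inhibitor of the pathway. For NF-kappa-B targets camera gave adjusted p = 1.07e-05, and adjusted p = 0.0809 with an estimated correlation. Coagulation and fibrinolysis genes had 7 higher and 1 lower of 15 (adjusted over the list alone, 8 and 1), with PLAT at 1.55 ± 0.14 and F3 at 1.14 ± 0.14. Coagulation genes had a camera adjusted p = 0.0037, and adjusted p = 0.136 with an estimated correlation. Cholesterol synthesis and uptake genes had 0 higher and 20 lower of 25 (adjusted over the list alone, 0 and 21), among them the lanosterol synthase gene LSS (-0.63 ± 0.08) and the squalene synthase gene FDFT1 (-0.65 ± 0.09). For cholesterol genes camera gave adjusted p = 1.73e-13, and adjusted p = 0.0514 with an estimated correlation. Fatty acid and triglyceride synthesis genes had 2 higher and 10 lower of 20 (adjusted over the list alone, 2 and 11), with ACSS2 at -0.77 ± 0.09 and the desaturase gene FADS2 at -0.69 ± 0.09. Fatty acid genes had a camera adjusted p = 0.000377, and adjusted p = 0.0744 with an estimated correlation.

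Mitosis and G2/M genes at 24 h had 17 higher and 0 lower of 35 (adjusted over the list alone, 22 and 0; median log2 fold change 0.25), with the cytokinesis gene ANLN at 0.58 ± 0.11. For mitosis genes camera gave adjusted p = 2.73e-07, and adjusted p = 0.117 with an estimated correlation. DNA replication and G1/S genes had 6 higher and 0 lower of 35 (adjusted over the list alone, 5 and 0), with the exonuclease gene EXO1 at 0.63 ± 0.10. For G1/S genes camera gave adjusted p = 0.0037, and adjusted p = 0.0764 with an estimated correlation. Ribosome biogenesis genes had 10 higher and 0 lower of 29 (adjusted over the list alone, 18 and 0). Ribosome biogenesis genes had a camera adjusted p = 9.77e-07, and adjusted p = 0.0621 with an estimated correlation. Among p53 targets 2 rose and 5 fell of 22 (adjusted over the list alone, 2 and 6), including the cell cycle inhibitor gene CDKN1A (-0.64 ± 0.11). For p53 targets camera gave adjusted p = 0.02, and adjusted p = 0.0633 with an estimated correlation. Of 15 stellate cell activation markers 7 rose and 1 fell (adjusted over the list alone, 8 and 3), with the smooth muscle actin gene ACTA2 at 0.71 ± 0.14 and the platelet-derived growth factor receptor gene PDGFRA at 1.44 ± 0.27. Activation markers had a camera adjusted p = 0.00463, and adjusted p = 0.0766 with an estimated correlation. Of 21 fibrillar and basement membrane collagens 10 rose and 3 fell (adjusted over the list alone, 10 and 4), and the list was not called (camera adjusted p = 0.203); COL1A1, a chain of type I collagen, rose by 0.43 ± 0.10 and COL4A5 fell by 0.61 ± 0.08. Of the 7 tested genes of the list of thrombin receptors and thrombin-binding proteins, which also holds the PAR2 gene F2RL1, 1 rose and 4 fell (adjusted over the list alone, 1 and 5). For the thrombin receptor list camera gave adjusted p = 0.00253, and adjusted p = 0.0621 with an estimated correlation. THBD rose by 1.82 ± 0.43 and SERPINE2, which encodes a thrombin inhibitor, fell by 0.91 ± 0.10. Immediate early genes went both ways, with 8 higher and 4 lower of 25 (adjusted over the list alone, 8 and 5; camera adjusted p = 0.428); MYC rose by 0.78 ± 0.08, KLF4 fell by 1.34 ± 0.16, and EGR1 (-0.70 ± 0.45) was not called. HBEGF, CCN2 and COL1A2 rose by 0.95 ± 0.13, 0.65 ± 0.12 and 0.59 ± 0.19, and IL6, TIMP1 and F2RL2 were not called.

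The histone list moved the other way from 4 h, with 2 rising and 0 falling of 19 at 24 h (adjusted over the list alone, 2 and 0). Histones had a camera adjusted p = 0.00849, and adjusted p = 0.13 with an estimated correlation. The mitosis and G1/S lists were also called higher at 24 h, so the histones do not stand for RNA quality alone. The epithelial markers KRT18, KRT8 and KRT7 rose by 0.78 ± 0.11, 0.77 ± 0.13 and 0.62 ± 0.17, and that list was not called (camera adjusted p = 0.0778; 3 rose and 0 fell of 6; adjusted over the list alone, 3 and 1). Hepatocyte, endothelial and macrophage markers were not called as lists at 24 h (camera adjusted p = 0.347, 0.721 and 0.743), with 1, 3 and 0 members called. Marker levels given here are averages over all libraries, in CPM without TMM scaling. The highest hepatocyte marker, SERPINA1, averaged 4.95 CPM. Other cell type lists held more abundant members. The highest were EGFL7 (endothelial, 63.4 CPM), CD68 (macrophage, 74.9 CPM, a gene outside the naming rule) and SOX9 (epithelial, 169 CPM). In all, 25 of 40 lists were called, 19 higher and 6 lower, and 4 of them with an estimated correlation. Without control 24 h replicate 12, 913 genes rose and 838 fell, without control 24 h replicate 13, 869 fell, and without thrombin 24 h replicate 14, 785 fell.

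**Figure D2:**
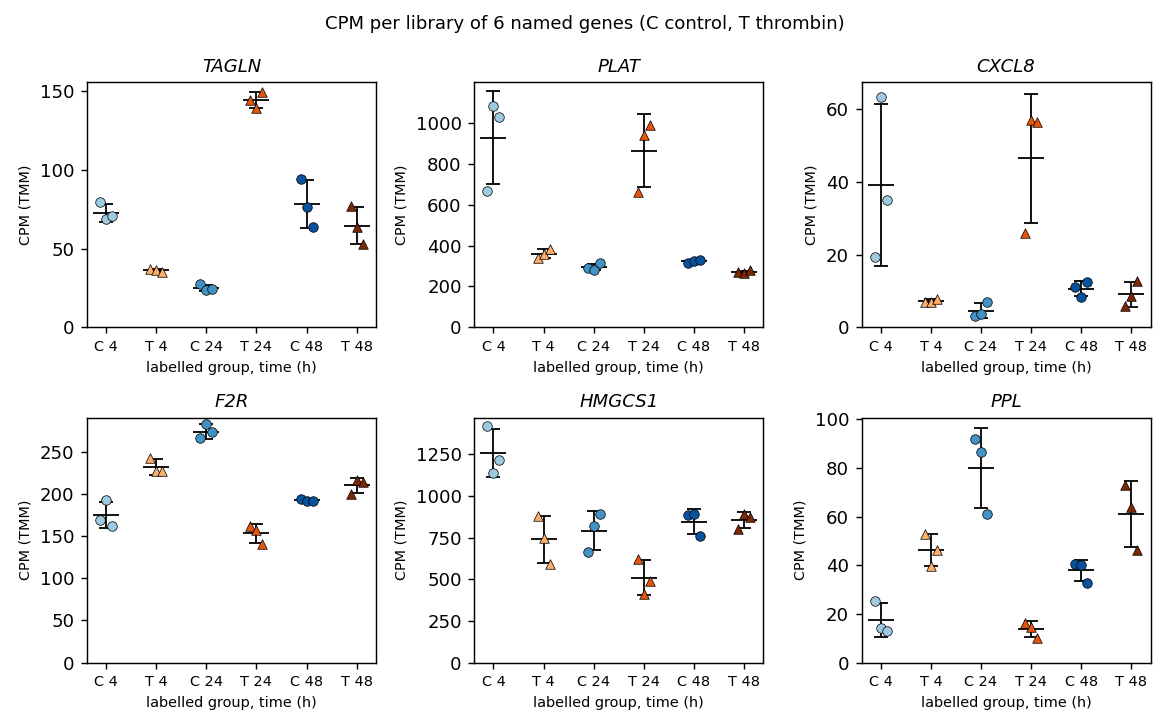
TMM-scaled CPM of 6 genes in each library, by labelled group (C control, T thrombin, time in h); bars are the mean and SD of 3 libraries. TAGLN, PLAT and CXCL8 are lower in thrombin than control at 4 h and higher at 24 h, F2R and PPL the reverse, and HMGCS1 is lower in thrombin at both times.

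**Figure D3:**
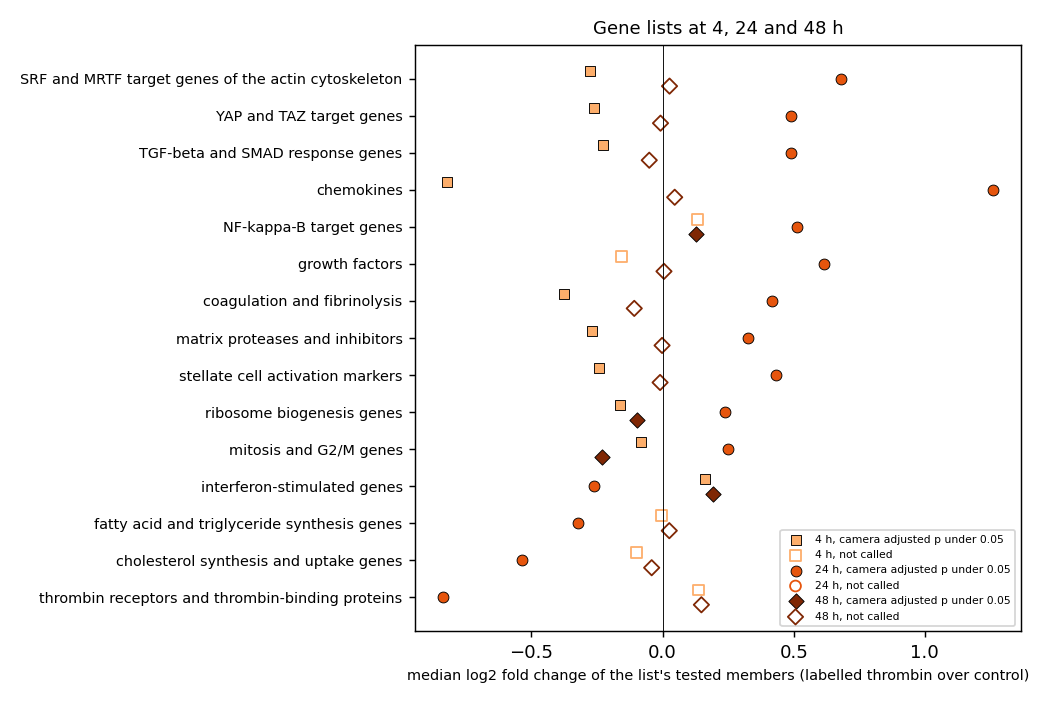
Median log2 fold change of the tested members of 15 gene lists at 4, 24 and 48 h, labelled thrombin over control; filled markers are lists called by camera with the preset correlation. SRF and MRTF targets stand at -0.28 at 4 h and 0.68 at 24 h.

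At 48 h edgeR called 0 of 15353 genes between the libraries labelled thrombin and control, with 1110 (7.23%) at an unadjusted p under 0.05 and a smallest adjusted p of 0.0646. The DESeq2 Wald test called 14 genes, 9 higher and 5 lower. TAGLN measured 78.1 ± 15.2 CPM in control and 64.6 ± 12.0 CPM in thrombin. F2R had a log2 fold change of 0.13 ± 0.08, CXCL8 of -0.24 ± 0.48, CCL2 of 0.03 ± 0.22, COL1A1 of -0.11 ± 0.10 and ACTA2 of 0.18 ± 0.14, none of them called. The 14 genes under DESeq2 were chosen for naming after their values were seen. The 9 higher were COL4A5 (log2 fold change 0.45, DESeq2 adjusted p = 0.00171), OLFML2A (0.49), PLEKHA4 (0.54), CSMD2 (0.53), CDKN1A (0.49), DOCK6 (0.51), UAP1L1 (0.37), NPEPL1 (1.14) and OLFML3 (0.49). The 5 lower were the TGF-beta-induced matrix gene TGFBI (log2 fold change -0.63, DESeq2 adjusted p = 0.000479), the insulin-like growth factor binding protein gene IGFBP6 (-0.56), the glycosyltransferase gene GCNT1 (-0.42), the pseudogene AURKAP1 (-0.38) and the claudin gene CLDN11 (-0.29). TGFBI alone was called lower by edgeR without control 48 h replicate 14, at -0.73.

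Some lists were called at 48 h although 0 of their members were called over all genes. Of 35 mitosis and G2/M genes, 34 had a value below 0 (median -0.23), and adjusted over the list alone 0 rose and 18 fell. For mitosis genes camera gave adjusted p = 3.18e-18, and adjusted p = 0.0752 with an estimated correlation. NDC80, a kinetochore gene, had -0.36 ± 0.09 and the cyclin gene CCNB1 -0.31 ± 0.08. Of 30 interferon-stimulated genes 26 had a value above 0 (median 0.19), and adjusted over the list alone 6 rose and 0 fell. Interferon-stimulated genes had a camera adjusted p = 3.09e-07, and adjusted p = 0.0752 with an estimated correlation. IFIT2 had 0.61 ± 0.16 and MX1 0.58 ± 0.18. Cytosolic ribosomal proteins had a median of 0.17 with 37 of 38 above 0 (adjusted over the list alone, 0 rose and 0 fell), and ribosome biogenesis genes a median of -0.10 (adjusted over the list alone, 0 and 0). For ribosomal proteins camera gave adjusted p = 0.000835, and adjusted p = 0.747 with an estimated correlation. Ribosome biogenesis genes had a camera adjusted p = 7.56e-05, and adjusted p = 0.194 with an estimated correlation. In all, 9 lists were called at 48 h, 7 higher and 2 lower, and 0 with an estimated correlation. Without control 48 h replicate 13 the count was 3. A split of the same libraries that mixed the labels called 13, more than the labelled groups.

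The thrombin effect differed between times for 4293 genes between 4 h and 24 h, for 97 between 4 h and 48 h and for 2126 between 24 h and 48 h. These counts rest on the labels. In a regrouping with all 4 h labels exchanged, all 24 h labels kept and the 48 h labels mixed, the count between 4 h and 24 h was 143. Across the 15353 genes, log2 fold changes at 4 h and 24 h had a Pearson correlation of -0.569 (Spearman -0.52). Of 961 genes called at both times, 948 had opposite signs and 13 the same sign; 468 were higher at 4 h and lower at 24 h, where independent lists would share 82.4, and 480 the other way, where they would share 76.7. No library is common to the 2 comparisons. Between 24 h and 48 h the correlation was -0.256, and between 4 h and 48 h it was 0.204. TAGLN, PLAT, CALD1, LOXL2, F3 and THBD all fell at 4 h and rose at 24 h, and F2R rose and then fell. The cholesterol list went both ways at 4 h, with 6 rising and 7 falling of 25 (adjusted over the list alone, 7 and 9; camera adjusted p = 0.281). DHCR7 and TM7SF2, which encode sterol reductases, rose by 0.47 ± 0.09 and 0.73 ± 0.15. HMGCS1, which encodes a cholesterol synthesis enzyme, and INSIG1, a feedback regulator of that pathway, fell at 4 h by 0.77 ± 0.14 and 0.72 ± 0.08. At 24 h HMGCS1 fell by 0.64 ± 0.14 and INSIG1 (-0.14 ± 0.08) was not called.

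**Figure D4:**
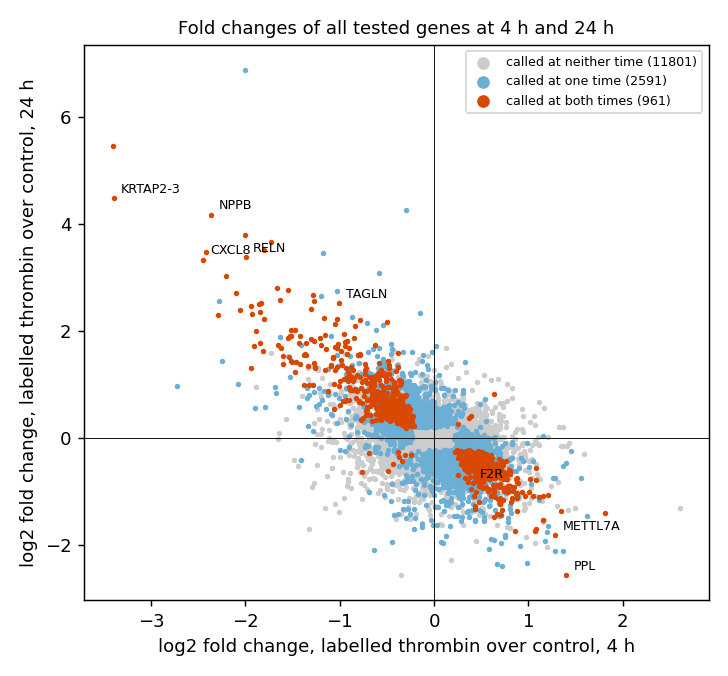
Log2 fold change of each of 15353 tested genes at 4 h (horizontal) and 24 h (vertical), labelled thrombin over control, coloured by whether a gene was called at neither, one or both times. The 961 genes called at both times lie mostly in the upper left and lower right quadrants, 948 of them with opposite signs.

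The SRF and MRTF list differed between 4 h and 24 h in 22 of 24 members, 21 with a higher and 1 with a lower effect at 24 h (adjusted over the list alone, 21 and 2), and between 24 h and 48 h in 17, of which 16 had a lower effect at 48 h (adjusted over the list alone, 1 higher and 20 lower). Between 4 h and 24 h camera gave adjusted p = 1.25e-14 for this list, and adjusted p = 0.00865 with an estimated correlation. Between 24 h and 48 h it gave adjusted p = 7.91e-14, and adjusted p = 0.011 with an estimated correlation. Between 4 h and 48 h 7 of its members had a higher effect at 48 h and 0 a lower one (adjusted over the list alone, 12 and 1). For SRF and MRTF targets camera gave adjusted p = 3.47e-10, and adjusted p = 0.0373 with an estimated correlation. Mitosis and G2/M genes had a lower effect at 48 h than at 24 h for 22 of 35 and a higher one for 0 (adjusted over the list alone, 0 and 27). Mitosis genes had a camera adjusted p = 2.53e-13, and adjusted p = 0.0632 with an estimated correlation. Cholesterol synthesis and uptake genes had a higher effect at 48 h than at 24 h for 15 of 25 and a lower one for 0 (adjusted over the list alone, 18 and 0). For cholesterol genes camera gave adjusted p = 5.31e-09, and adjusted p = 0.081 with an estimated correlation. The count of 97 genes between 4 h and 48 h was 236 by DESeq2 and 290 without control 4 h replicate 12. It was 41, 44 and 47 without control 4 h replicates 13 and 14 and thrombin 4 h replicate 13 in turn, and 45, 46 and 47 without control 48 h replicate 13 and thrombin 48 h replicates 13 and 14 in turn.

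Control-labelled libraries also differed between times. Between 4 h and 24 h, 1243 genes were higher and 1097 lower at 24 h. By the naming rule, the largest called increases were in PPL (2.19 ± 0.25), CDK18 (1.58 ± 0.16), the tropomodulin gene TMOD1 (1.44 ± 0.17), the noncoding RNA gene MIAT (1.36 ± 0.34) and PLXDC1 (1.32 ± 0.16), and the largest called decreases in KRTAP2-3 (-4.48 ± 0.48), CXCL8 (-3.09 ± 0.49), KRT34 (-2.80 ± 0.27), ESM1 (-2.60 ± 0.51) and SERPINB2 (-2.53 ± 0.55). Between 24 h and 48 h, 413 genes were higher and 527 lower at 48 h. MYOCD, which encodes the SRF coactivator myocardin, was higher by 2.01 ± 0.32, TAGLN by 1.64 ± 0.12, the matrix Gla protein gene MGP by 1.51 ± 0.31, MYPN by 1.25 ± 0.20, and the activin gene INHBA rose from 9.93 ± 1.54 to 23.1 ± 1.67 CPM. MYO7A (-1.86 ± 0.24), GASK1B (-1.60 ± 0.39), the connexin gene GJB2 (-1.45 ± 0.27), SLCO2B1 (-1.31 ± 0.27) and METTL7A (-1.23 ± 0.23) fell most among the genes that the rule admits.

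Mitosis and G2/M genes in control libraries had 0 higher and 16 lower of 35 at 24 h than at 4 h (adjusted over the list alone, 0 and 25), and 17 higher and 0 lower at 48 h than at 24 h (adjusted over the list alone, 22 and 0). The control 24 h libraries enter both of these comparisons and that of thrombin with control at 24 h, so list results of these comparisons are not independent. In controls, 24 h against 4 h gave a camera adjusted p = 2.19e-09, and adjusted p = 0.108 with an estimated correlation. For 48 h against 24 h it gave adjusted p = 2.81e-13, and adjusted p = 0.125 with an estimated correlation. Interferon-stimulated genes had 11 higher and 1 lower of 30 at 24 h than at 4 h (adjusted over the list alone, 13 and 1). For interferon-stimulated genes camera gave adjusted p = 0.000212, and adjusted p = 0.094 with an estimated correlation. Histone genes had 0 higher and 7 lower of 19 over the same interval (adjusted over the list alone, 0 and 8). Histones had a camera adjusted p = 1.19e-05, and adjusted p = 0.0848 with an estimated correlation. The mitosis list was lower over that interval too, so RNA quality and the cell cycle again cannot be told apart. The count of 2340 genes between 4 h and 24 h was 1557, 1509, 1286 and 1403 without control 4 h replicates 13 and 14 and control 24 h replicates 12 and 13 in turn. The count of 940 between 24 h and 48 h was 214, 265, 300 and 358 without control 24 h replicates 12 and 13 and control 48 h replicates 12 and 13 in turn.

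Across all pairs of labelled groups, the control 4 h libraries differed from thrombin 24 h in 513 genes and from control 24 h in 2340, and the thrombin 4 h libraries differed from control 24 h in 11 and from thrombin 24 h in 2322. The thrombin 48 h libraries differed from control 24 h in 55 genes and from thrombin 4 h in 170.

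**Figure D5:**
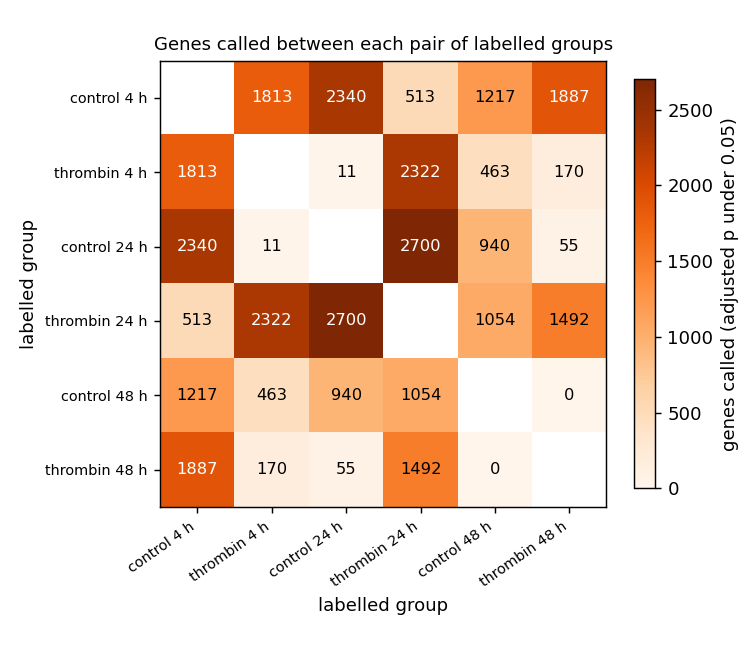
Number of genes called by edgeR (of 15353) between each pair of the 6 labelled groups of 3 libraries. The smallest counts are 0 between the 48 h groups and 11 between thrombin 4 h and control 24 h, and the highest is 2700 between control 24 h and thrombin 24 h.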

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

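The 2 tests of exchanged treatment labels and the 2 split tests of the correlations with 48 h were chosen only after the result was seen; the other tests of explanations were written beforehand. Single outlying libraries were not tested within groups of 3.

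The thrombin effect differed between times for many genes by the test of the difference itself. Between 4 h and 24 h it differed for 4293 genes. Of 100 random splits of the libraries within each time, the real one included, 1 gave as many. The highest other count was 3469, in a split that kept all 24 h labels and mixed those at 4 h. A random grouping of these libraries can thus be excluded at the 0.05 level. The splits do not test a difference between times, since a group difference at 24 h alone gave a high count. Chance differences between cultures were not tested either, since the spread between libraries may be technical. Between 24 h and 48 h it differed for 2126 genes, and again 1 of 100 splits gave as many, with 1337 as the highest other (again with all 24 h labels kept). Between 4 h and 48 h it differed for 97 genes, and 2 of 100 splits gave as many, with 804 as the highest other. That split called several times the real count. It kept 0 of 6 labels at 4 h, 6 of 6 at 24 h and 4 of 6 at 48 h, so both labelled 4 h groups stayed whole in it, with their labels exchanged, and what its count rests on was not tested further. In the same split the effect differed between 4 h and 24 h for 143 genes, against 4293 as labelled. The count of 4293 thus rests on the labels at these times. Mixed 48 h labels enter the shared spread, so 143 is not the count for an exchange at 4 h alone.

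By the naming rule, the largest differences of the log2 thrombin effect, 24 h minus 4 h, were positive in KRTAP2-3 (7.88), NPPB (6.53), CXCL8 (5.78), NFATC2 (5.39) and RELN (5.38) and negative in PPL (-3.96), METTL7A (-3.10), CDK18 (-2.78), GASK1B (-2.67) and C3 (-2.28). Sizes and ranks of such differences rest on the labels. KRTAP2-3 had -3.40 at 4 h and 4.48 at 24 h, and PPL 1.40 and -2.55. With labels exchanged at one of these times, its effects would share a sign and the difference would be smaller for each of these 2 genes. For 48 h minus 4 h they were positive in RELN (2.31), KRT34 (2.27), FOLR3 (2.01), DRGX (1.94) and the smooth muscle actin gene ACTG2 (1.89), and negative in GLI1 (-1.09), MYH16 (-1.01), AK5 (-0.83), HOXC6 (-0.79) and the planar polarity gene VANGL2 (-0.72). For 48 h minus 24 h they were positive in PPL (3.24), GASK1B (2.47), MYO7A (2.38), METTL7A (2.14) and SLITRK4 (2.10), and negative in NPPB (-5.54), KRTAP2-3 (-5.23), NFATC2 (-4.11), the retinal reductase gene DHRS3 (-3.69) and CXCL8 (-3.57).

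The first pattern is that fold changes at 4 h and 24 h pointed in opposite directions across genes, with TAGLN, PLAT and CXCL8 lower and then higher, and a correlation of -0.569; 1 of 100 splits, the real one included, gave a correlation as far from 0, with 0.486 the highest size among the others, so chance can be excluded. As the whole cause, a single library out of place is argued against, since the correlation of differences of mean log2 CPM (-0.581 over all 12 libraries) stayed at -0.521 or further below 0 with each library left out in turn, and trends with gene length and expression are argued against, since it was -0.597 after both were removed in 14802 genes (96.4%). Over the 9 combinations of single differences by replicate number the correlation lay between -0.489 and -0.0879, weakest for the libraries numbered 12 at both times. An exchange of treatment labels at one of these times may account for the pattern. The unlike-labelled pairs differed in 11 genes (thrombin 4 h and control 24 h) and 513 (control 4 h and thrombin 24 h). The like-labelled pairs differed in 2322 and 2340. By Spearman correlation, most 4 h and 24 h libraries were nearest an opposite-labelled library of the other time. The exceptions were control 4 h, thrombin 4 h and thrombin 24 h replicates 12, each nearest a 48 h library among other groups. A response of the cells that reverses between 4 h and 24 h, together with a drift of the control cultures, was not tested and stays open. The 48 h libraries do not settle which time would carry an exchange. As labelled, their fold changes went with those at 4 h (correlation 0.204) and against those at 24 h (-0.256). With the 24 h labels exchanged, 4, 24 and 48 h would go together. With the 4 h labels exchanged, 48 h would go against both unless its own labels were exchanged too. Chance was not excluded for these correlations with 48 h, and the 48 h labels are themselves in doubt.

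The second pattern is that 0 genes were called at 48 h by edgeR (1110 at an unadjusted p under 0.05; 14 by DESeq2). A wider spread between replicates is argued against, since the median SD of log2 CPM within groups was 0.979 times that at 24 h (0.139 against 0.142). A library of each 48 h group standing in the place of the other is argued against as well, since the highest count of another split of the 6 libraries was 3 genes. A count of splits says nothing here, since with a real count of 0 all 10 of the 10 splits reach it whatever the data, and 10 splits are too few for a share under 0.05. A response that had ended by 48 h, or thrombin no longer active in the medium, was not tested and stays open.

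The third pattern is that fold changes at 48 h went with those at 4 h (correlation 0.204) and against those at 24 h (-0.256), across genes, which are not independent replicates. For differences of mean log2 CPM these correlations were 0.222 and -0.269. Within 4 h and 48 h, 5 of 100 splits, the real split included, gave a correlation as far from 0 (highest other 0.376). Within 24 h and 48 h, 4 of 100 did (highest other 0.308). The share for 24 h lay just under 0.05, and both tests were chosen after the correlations were seen. Chance is therefore not taken as excluded for 4 h or for 24 h. Whether labels could have been exchanged at 48 h as well cannot be told apart from the labelled order: of the unlike-labelled pairs across 24 h and 48 h, thrombin 48 h and control 24 h differed in 55 genes and control 48 h and thrombin 24 h in 1054, and of the like-labelled pairs the controls differed in 940 and the thrombin groups in 1492. With 1054 between 940 and 1492, the 2 unlike-labelled pairs do not both lie below the like-labelled ones, and the lack of called genes at 48 h keeps this open.

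For single comparisons of 3 libraries with 3 there are 10 splits, the real one included, too few for a share under 0.05. At 4 h the real split called 1813 genes and the highest other 1, with 1 split as high as the real one. At 24 h the counts were 2700 and 0, again with 1 split. For control 24 h against control 4 h they were 2340 and 0, and for control 48 h against control 24 h 940 and 0, with 1 split each. Of gene lists, the real split called 17 at 4 h and the highest other also 17 (2 of 10 splits as high), 25 at 24 h and 16 (1 split), and 9 at 48 h and 13 (3 splits).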

How the results depend on the processing

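The fits without the 4 h libraries and without the libraries numbered 12 were chosen only after the data were seen. Of 381 named gene values, 0 reversed while called under any alternative, and 21 uncalled values changed sign without being called under either setting. All of these alternatives kept the treatment labels, so they do not test directions against an exchange of labels. DESeq2 size factors left all 381 on their side of the threshold. With single libraries left out, 2295 of 2466 named gene values kept their side, 158 were no longer called and 13 became called. In the fit of the 6 libraries of one time, 10 of 330 were no longer called and 7 became called, without the libraries numbered 12 it was 9 and 11 of 381, and without the 4 h libraries 1 and 1 of 227. Among values with an adjusted p, no call ended by the DESeq2 Wald test (7 of 378 became called), with no low-count filter (22 of 381), with the replicate block (5 of 381) or with that block in DESeq2 (10 of 378). Values to which DESeq2 gave no adjusted p were left out, so 378 and not 381 were compared. A call lost in that way was not counted. An estimated correlation ended 47 of 51 list calls, fry ended 10, the replicate block 1 and DESeq2 size factors 0, and leaving out single libraries ended 34 of 306. The cause was not tested for any of the values that follow, except that leaving out libraries leaves fewer samples.

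By the DESeq2 Wald test, 9 genes were higher and 5 lower at 48 h, 1 of them at least 2-fold (NPEPL1, named after its value was seen), and the effect at 4 h differed from that at 48 h for 236. With no low-count filter 25 were higher and 25 lower at 48 h, 3 at least 2-fold (NPPB, NPEPL1 and ZNF467, named after their values were seen), and the counts were 381 between the effects at 4 h and 48 h and 1524 between controls at 24 h and 48 h. In the fit of the 6 libraries of one time, 570 genes were higher at 4 h and 2 lower at 48 h (TGFBI and IGFBP6, named after their values were seen). Without the libraries numbered 12, 1772 genes were higher and 1788 lower at 4 h, 253 at least 2-fold; at 48 h 4 were higher (IFIT2, MME, CSMD2 and OLFML2A) and 1 lower (IGFBP6), all named after their values were seen; the effect differed between 4 h and 48 h for 1133 genes, and controls between 24 h and 48 h for 347. Without the 4 h libraries, 1549 genes were higher and 1418 lower at 24 h. With an estimated correlation 0 lists were called at 4 h, 4 at 24 h and 0 at 48 h, and by fry 4 at 48 h.

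With the replicate block, 1 gene was lower at 48 h (TGFBI, named after its value was seen) and the effect differed between 4 h and 48 h for 163 genes; with the replicate block in DESeq2, 21 were higher and 10 lower at 48 h, 2 at least 2-fold (NPEPL1 and ZNF467, likewise), and 270 differed between 4 h and 48 h. The replicate numbers were not shown to pair the samples: 0 of 9 pair correlations were over 0.1 (-0.093 to 0.057), and 8 of 18 libraries correlated best with one of their own number.

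With single libraries left out, the genes higher at 4 h ranged from 425 to 1283 and those lower from 415 to 1114 (lowest without thrombin 4 h replicate 14, highest without thrombin 4 h replicate 12). Genes at least 2-fold changed at 4 h ranged from 94 to 181. At 24 h, 913 to 1283 were higher (lowest without control 24 h replicate 12) and 785 to 1206 lower (lowest without thrombin 24 h replicate 14), and 341 to 410 changed at least 2-fold. At 48 h 0 were higher, and 0 to 1 lower (TGFBI, without control 48 h replicate 14). The effect differed for 3478 to 4710 genes between 4 h and 24 h, 41 to 290 between 4 h and 48 h (without control 4 h replicates 13 and 12) and 1465 to 2245 between 24 h and 48 h. Controls differed in 1286 to 2314 genes between 4 h and 24 h and in 214 to 1135 between 24 h and 48 h, both lowest without control 24 h replicate 12. Lists called ranged from 13 to 17 at 4 h, 22 to 29 at 24 h and 3 to 11 at 48 h (lowest without control 48 h replicate 13). At these depths F2RL3, with 0 to 2 raw counts in each library, fell under the low-count filter and was not tested.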

Other observations

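The list tests between control libraries and between times were chosen only after the data were seen; those of thrombin against control were fixed beforehand, and none of the list calls below held with an estimated correlation. At 24 h, interferon-stimulated genes were lower in the libraries labelled thrombin, with 2 rising and 9 falling of 30 (adjusted over the list alone, 2 and 10). For interferon-stimulated genes camera gave adjusted p = 0.00463, and adjusted p = 0.13 with an estimated correlation. IFI44 fell by 1.29 ± 0.20 and STAT2, a transcription factor of the interferon response, by 0.54 ± 0.08, while SAMD9 rose by 1.07 ± 0.15. Lysosome and autophagy genes had 1 higher and 8 lower of 28 (adjusted over the list alone, 3 and 10), with the cathepsin gene CTSS at -1.37 ± 0.21. Lysosome genes had a camera adjusted p = 0.0102, and adjusted p = 0.0764 with an estimated correlation. Amino acid response and ATF4 target genes had 9 higher and 2 lower of 29 (adjusted over the list alone, 9 and 3), with the amino acid transporter gene SLC7A5 at 1.67 ± 0.14. For ATF4 targets camera gave adjusted p = 0.02, and adjusted p = 0.453 with an estimated correlation. Integrins had 6 higher and 2 lower of 17 (adjusted over the list alone, 7 and 5), with the fibronectin receptor subunit gene ITGA5 at 1.27 ± 0.10 and ITGB8 at 1.26 ± 0.13. Integrins had a camera adjusted p = 0.0343, and adjusted p = 0.366 with an estimated correlation. Cytokines had 5 higher and 0 lower of 15 (adjusted over the list alone, 7 and 0), with LIF at 2.24 ± 0.23 and IL1B at 1.90 ± 0.33. For cytokines camera gave adjusted p = 0.0378, and adjusted p = 0.366 with an estimated correlation. The endothelin gene EDN1 rose by 1.61 ± 0.19 and its receptor gene EDNRA fell by 1.37 ± 0.27.

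At 4 h, matrix proteases and inhibitors had 1 higher and 5 lower of 25 (adjusted over the list alone, 2 and 10), and stellate cell activation markers 0 higher and 3 lower of 15 (adjusted over the list alone, 0 and 6). For matrix proteases camera gave adjusted p = 0.00887, and adjusted p = 0.178 with an estimated correlation. Activation markers had a camera adjusted p = 0.0186, and adjusted p = 0.197 with an estimated correlation. At 48 h, immediate early genes had a median log2 fold change of 0.18 with 20 of 25 above 0 (adjusted over the list alone, 0 rose and 0 fell), and collagens a median of 0.11 (adjusted over the list alone, 3 rose and 0 fell). For immediate early genes camera gave adjusted p = 0.00165, and adjusted p = 0.194 with an estimated correlation. Collagens had a camera adjusted p = 0.0148, and adjusted p = 0.702 with an estimated correlation.

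In control libraries, SRF and MRTF targets had 1 higher and 13 lower of 24 at 24 h than at 4 h (adjusted over the list alone, 2 and 15), and chemokines 0 higher and 6 lower of 12 (adjusted over the list alone, 0 and 7). For SRF and MRTF targets camera gave adjusted p = 1.19e-05, and adjusted p = 0.0848 with an estimated correlation. Chemokines had a camera adjusted p = 0.000804, and adjusted p = 0.0848 with an estimated correlation. From 24 h to 48 h, YAP and TAZ targets had 7 higher and 0 lower of 21 (adjusted over the list alone, 15 and 0). For YAP and TAZ targets camera gave adjusted p = 3.03e-09, and adjusted p = 0.125 with an estimated correlation. The control comparisons share libraries with each other and with the thrombin comparisons. All of these directions rest on the labels of the groups.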
